A study of Mus musculus with 18 samples.

How the data were processed

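RNA of primary mouse hepatocytes was measured on 18 one-color Affymetrix arrays of 45101 probe sets each. Per the labels' protocols, cells of 1 animal or of a pool of up to 3 were cultured on collagen I, kept in serum-free medium with dexamethasone, and moved to medium without it before stimulation. RNA was extracted with an RNeasy kit and biotin-labelled with the one-cycle kit, per the labels' protocols. The deposited values were log2 expression signals, per the labels, and ran from 2.095 to 15.049; the summarization and normalization the authors used to make them are not given in the sources used here. The sorted values of the arrays differed from their mean by at most 0.118, so the values were close to quantile-normalized as deposited, and they were used without further scaling. All columns belonged to a sample (0 were left over).

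Groups were read from the stimulus and time in the labels: 1 control at -5 h, placed before starvation by inference from the hours of the protocol, 5 later controls, 4 arrays with IL-6 and 8 with IL-6 plus HGF, and no array was left out. The label design also speaks of HGF given alone, and such arrays were not analysed here. The grouping, the comparisons, the alternatives, the 29 gene lists and the rule for naming genes were set before the data were examined.

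Of the probe sets 64 were controls. Over all 45101 probe sets, controls included, 34958 had a single gene symbol, 932 had several and 9211 had none. Symbols came from the Entrez identifier for 34754 probe sets, 204 kept the symbol of the array annotation and 0 were changed. For each gene the probe set with the highest mean over the 18 arrays was used, which left 18193 genes, 9010 of them with more than 1 probe set. No filter on dim genes was applied. The lists held 858 symbols, of which 798 were measured.

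Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and moderated eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. IL-6 against control used 17 arrays as means of 4 cells: control at 0 and 4 h, IL-6, control at 8 to 24 h, and IL-6 plus HGF. The change of effect after HGF was a contrast in the same fit. IL-6 plus HGF against control at matched times used 6 arrays at 8, 12 and 24 h with time as a block, which left 2 residual degrees of freedom. The pairing came from the hours in the labels; replicate numbers were not used to pair, since no source states that equal numbers share an animal or a day. Time trends were slopes on log2 of the hours under IL-6 plus HGF (8 arrays), the difference of such slopes between IL-6 plus HGF and control (12 arrays), and slopes on log2 of the hours plus 1 in control (5 arrays). The control at -5 h was compared with the 5 later controls. Differences are in log2 units, and slopes in log2 units per doubling of the time variable.

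Gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over the lists within a comparison. Members past the threshold were counted over all genes and again when adjusted over the list alone. The rule named the 8 largest rises and 8 largest falls among the genes past the threshold, up to 4 passing members of each list (or 2 as values where none passed), and 11 fixed genes. Where fewer than 10 genes passed, the 10 with the smallest p were taken as values. Symbols that are only clone or model names were left out, and the text uses fewer genes than the rule allows. For the named genes with more than 1 probe set the direction was checked over all of them; among genes named in the text it was shared in 7 of 7, 32 of 39, 5 of 5, 14 of 17, 5 of 5, 5 of 7 and 10 of 10 such genes in the order IL-6, matched times, change of effect, trend, trend difference, -5 h and control trend.

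The alternatives were quantile normalization, centring of each array on its median, a filter on genes under the 40th percentile of mean signal, an intensity trend with robust variance, the mean of all probe sets, a log2 difference of at least 1, and leaving out each array or matched pair. Others were further choices of controls and of arrays, the matched times without the time block, over the 4 cells or with a natural spline of time with 3 degrees of freedom (splines 4.3.3), hours in place of their logarithm, the fits without 24 h arrays, camera with the correlation estimated per list, and fry. A mean of nuclear RNAs per array as covariate was added after the data had been seen. The list directions were checked under the 3 scalings.

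The fits were tested on simulated data for 18193 genes, with 67, 67 and 66 genes changed by 0.5, 1 and 2 log2. For the trend comparisons these sizes were slopes in log2 per doubling of the time variable. Over the hours sampled such a slope makes a larger change than a difference of the same size. Recovery is therefore not comparable between trends and differences. Of genes changed by 1 log2, 91% were recovered for IL-6, 71.6% at matched times, 76.1% for the change of effect, 97% for the trend, 95.5% for the trend difference, 56.7% for the array at -5 h and 100% for the control trend. Of genes changed by 0.5 log2, 53.7%, 19.4%, 23.9%, 74.6%, 64.2%, 4.5% and 91% were recovered in that order. False calls made up 3%, 0.8%, 5.1%, 6.7%, 4.4%, 4.6% and 3.5% of the calls. The simulated noise was independent between genes and arrays, without drift over time or array effects. The share of false calls in the measured data can therefore differ.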

Results

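Gene expression was measured in primary mouse hepatocytes, the parenchymal cells of the liver, taken from male C57BL/6N mice and kept below confluence on collagen I. IL-6, a cytokine that drives the hepatic acute-phase response through the transcription factor STAT3, was given at 40 ng/ml from 0 h. HGF, the ligand of the receptor tyrosine kinase Met and a growth factor for hepatocytes, was added at 40 ng/ml at 4 h. The 18 arrays were 1 control at -5 h, 5 controls at 0, 4, 8, 12 and 24 h, 4 arrays with IL-6 alone at 1, 2, 3 and 4 h, and 8 arrays with IL-6 plus HGF at 5, 6, 7, 8, 9, 10, 12 and 24 h. The series addressed how the transcriptome changes over time when IL-6 precedes HGF, with hepatocyte proliferation in view. Each condition and time was measured on 1 array, so the times of a stimulus took the place of replicates and the spread includes change over time. No source states that the dishes came from separate animals, so all p-values measure only the spread between these dishes and times. None of the 18 arrays had IL-6 alone after 4 h or HGF alone, which leaves the addition of HGF and the longer exposure to IL-6 confounded. Array medians lay between 5.47 and 5.57 on the log2 scale, the mean correlation of an array with the others lay between 0.985 and 0.994, and the number of arrays limits the precision.

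IL-6 alone was set against control over the first 4 hours. Socs3, which encodes a feedback inhibitor of IL-6 receptor signalling, was 11.4-fold higher with IL-6, at 10.87 ± 0.17 (log2 mean ± SD, n = 4) against a mean of 7.36 in the controls at 0 and 4 h. Cebpd, a transcription factor of acute-phase genes, was 6.76-fold higher, at 11.23 ± 0.25 (SD, n = 4) against 8.47. The glycosyltransferase gene Gcnt2 was 2.65-fold higher, at 10.37 ± 0.10 (SD, n = 4) against 8.96, and Efna1, which encodes a ligand of Eph receptors, was 2.27-fold higher, at 9.34 ± 0.16 (SD, n = 4) against 8.16. These 4 genes were higher and 0 were lower among 18193 genes in the limma fit, in which 656 genes had an unadjusted p under 0.05 and chance alone would give 910. The log2 differences were 3.51 ± 0.32 (SE) for Socs3 (adjusted p = 2.44e-05), 2.76 ± 0.21 for Cebpd (2.01e-06), 1.40 ± 0.10 for Gcnt2 (9.72e-07) and 1.19 ± 0.16 for Efna1 (0.00378). All 4 were past the threshold in each fit of the full set of arrays, while Efna1 missed it without the control at 0 h (adjusted p = 0.0989) or without that at 4 h (0.122). With hours as a covariate in the 6 arrays of these times limma called 8 genes higher and 1 lower, and against all 5 controls it called 20 higher and 2 lower.

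Of the 23 measured members of the IL-6 and STAT3 list, 21 had positive differences in the first 4 hours, with a median of 0.52. Only Socs3 and Cebpd passed over all genes, and 10 members were higher when adjusted over the list alone. The list was shifted upward by camera (adjusted p = 7e-24, and adjusted p = 0.00145 with an estimated correlation). Junb, an immediate early gene, differed by 0.96 without passing (adjusted p = 0.453), as did Pim3 by 0.70 (0.0887). Junb passed with hours as a covariate (adjusted p = 0.0226) and against all 5 controls (0.0167), and Pim3 after centring (0.0451), against all 5 controls (0.00491) and without the IL-6 array at 4 h (0.025). Among the 35 positive acute-phase proteins 0 passed over all genes in limma and 3 were higher when adjusted over the list alone. Steap4 differed by 1.53 (adjusted p = 0.0567), the fibrinogen chain gene Fgb by 0.41 (0.914), and the serum amyloid genes Saa1 and Saa2 by -0.07 each. Saa1 lay near the top of the array scale on all arrays, controls included, where a rise may not have been measurable. Steap4 passed after quantile normalization (adjusted p = 0.0468), with hours as a covariate (0.0441) and without the IL-6 array at 1 h (0.0106), and Fgb against all 5 controls (0.047). That list had a median of 0.07 and a camera adjusted p of 0.00549, which was lost at adjusted p = 0.999 with an estimated correlation. Of the 35 immediate early and ERK feedback genes 0 passed and 1 was higher when adjusted over the list alone, with a median of 0.16, a camera adjusted p of 0.0149 and adjusted p = 0.999 with an estimated correlation. Of the 19 glycolysis genes 0 passed on either scale of adjustment, with a median of 0.05 and a camera adjusted p of 0.0149 (adjusted p = 0.0788 with an estimated correlation). Both of the latter calls were also lost without the IL-6 array at 1 h, which took the number of called lists from 5 to 3. Without the control at 4 h the positive acute-phase (adjusted p = 0.0992), immediate early (0.517) and glycolysis (0.188) calls were lost. Glycolysis was also lost without the control at 0 h (0.0561) and against all 5 controls (0.366), and the immediate early list without the IL-6 array at 2 h (0.0625).

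Markers of Kupffer cells, the resident macrophages of the liver, were lower with IL-6 over the same 4 hours. Of 21 measured markers 19 had negative differences, with a median of -0.45. None passed over all genes in limma (0 of 21), and 13 were lower when adjusted over the list alone. Camera gave an adjusted p of 3.9e-18 for the list, and adjusted p = 0.00269 with an estimated correlation. The scavenger receptor gene Cd163 differed by -0.94 (adjusted p = 1) and Vsig4, a complement receptor of these cells, by -0.64 (0.988). Relative to the control at 0 h the mean of these markers lay between -0.39 and -0.50 on the 4 IL-6 arrays. In control it was -0.10 at 4 h, -0.43 at 24 h and -0.50 at -5 h. Markers of liver endothelial cells had a median difference of -0.05 (camera adjusted p = 0.39). In this window 0 of 25 G1 and G1/S genes (median -0.08, camera adjusted p = 0.472), 0 of 39 DNA replication genes (-0.05, 0.753), 0 of 36 G2 and mitosis genes (-0.04, 0.999) and 0 of 46 drug metabolism genes (0.02, 0.753) passed in limma.

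**Figure D1:**
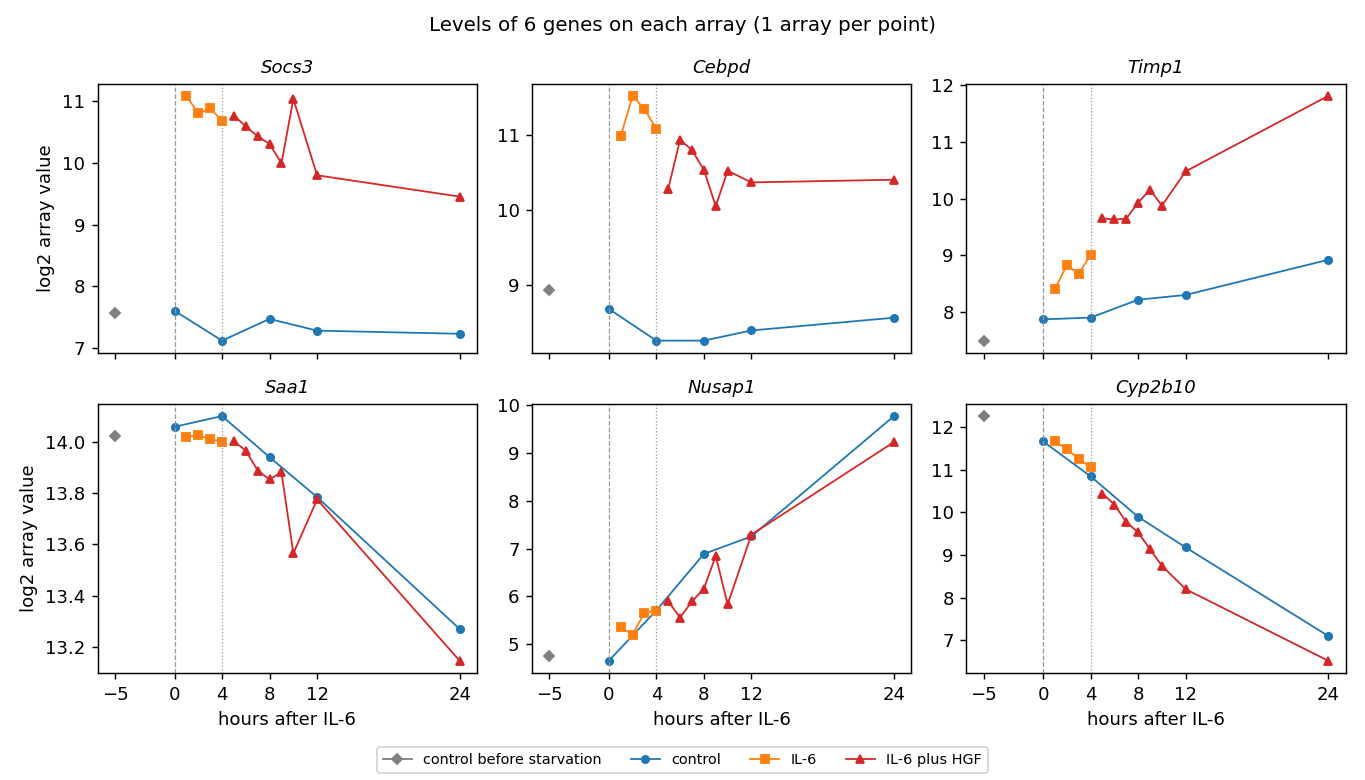
Log2 array value against hours after IL-6 for 6 genes, 1 array per point, coloured by stimulus; the dashed line marks IL-6 at 0 h and the dotted line HGF at 4 h. Socs3 and Cebpd lay above control on every stimulated array, Timp1 reached 11.82 at 24 h against 8.92 in control, and Saa1 stayed between 13.1 and 14.1 on all arrays. The highest value of any probe set was 15.049, so a rise of Saa1 may not have been measurable.

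IL-6 plus HGF was set against control at 8, 12 and 24 h, the 3 times measured in both. Genes of the IL-6 response stayed high: Socs3 was 5.77-fold higher (2.53 ± 0.12 log2, SE, 3 pairs; adjusted p = 0.00102) and Cebpd 4.07-fold higher (2.03 ± 0.10; 0.00102). Timp1, an inhibitor of metalloproteinases, was 4.82-fold higher (2.27 ± 0.20; 0.00302), Rdh10, a retinol dehydrogenase, 4.48-fold higher (2.16 ± 0.10; 0.00102) and the cytokine gene Il24 4.66-fold higher (2.22 ± 0.26; 0.00604). The kidney injury marker Havcr1 rose by 2.09 log2, Lmcd1 by 2.21 and the matrix gene Fbln2 by 1.76. The largest declines were in genes of liver metabolism: Ugt2b35, a glucuronosyltransferase, was 9.27-fold lower (-3.21 ± 0.17; 0.00128), the alcohol dehydrogenase gene Adh1 8.89-fold lower (-3.15 ± 0.37; 0.00611) and Akr1c14 6.77-fold lower (-2.76 ± 0.09; 0.000523). Baat, which conjugates bile acids, differed by -2.73, Chdh by -2.64, Akr1c19 by -2.43, and Arg1, the last enzyme of the urea cycle, by -2.40, with -0.64 in the pair at 24 h alone. Ddc differed by -3.02, although its other probe set differed by 0.02. Each of these genes moved the same way in 3 of 3 pairs. All 4 genes higher in the first 4 hours with IL-6 were again higher here.

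In limma 461 genes were higher and 1176 lower at the matched times, of 18193 tested, and 4531 had an unadjusted p under 0.05. Of these, 49 were higher and 150 lower by at least 1 log2. The higher genes were 28.2% of the calls, against 34.9% after quantile normalization and 19.2% after centring each array on its median. Without the pair at 8 h limma called 228 higher and 615 lower, without that at 12 h 178 and 407, and without that at 24 h 207 and 552, and 778, 540 and 695 of the 1637 genes were among them. Without the time block, where change over time adds to the spread, it called 48 and 94. Socs3, Cebpd, Rdh10, Il24, Ugt2b35, Chdh, Akr1c19 and Ddc then still passed, whereas Timp1, Lmcd1, Havcr1, Fbln2, Adh1, Akr1c14, Baat, Arg1 and most genes named in the next paragraphs did not. With an intensity trend and robust variance Adh1 (adjusted p = 0.111), Baat (0.104), Arg1 (0.245), Lmcd1 (0.0864), Havcr1 (0.114) and Fbln2 (0.262) missed the threshold, as did Ugt2b5 (0.131), Tdo2 (0.219), Fmo5 (0.0607), Cd36 (0.0835), Saa4 (0.0667), Ahsg (0.0922), Slc7a11 (0.061), Cldn4 (0.0742) and Cd68 (0.0543), which are named in the next paragraphs. With a spline of time over 17 arrays it called 1056 and 2096. Over the 4 cells of 17 arrays it called 516 and 1092, and 322 and 560 when a nuclear RNA index was added to that fit as covariate; 1031 and 641 of the 1637 genes were among them. The hours are not matched in these cells, and Lmcd1, Fbln2, Baat, Arg1, Masp1, F13b, F10, Ahsg, Apoa4, Cd44, Tk1, Cenpf, Ttk, Mki67, Ccnb2, Bhmt, Slc2a2, Pkm, Ifit1, Creb3l3, Dhcr7, Cd68, Ankrd1, Tat and Rgs5 were not called there. Camera called 18 of 29 lists, while camera with an estimated correlation and fry each called 0, so every list call at these times was lost under both. The fit of the matched times left 2 residual degrees of freedom, which limits what both can call. Lists as unlike as drug metabolism and interferon response shared an adjusted p of 0.344 with an estimated correlation. At these times such a loss alone does not argue against a shift, nor do the camera calls alone establish one. On these arrays the nuclear RNA Malat1, chosen after its values were seen, differed by 1.56 (adjusted p = 0.00901), a call lost with an intensity trend and robust variance (0.0661), without the time block (0.0764) and in the 4 cells (0.0643).

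At the matched times 11 of 23 members of the IL-6 and STAT3 list were higher and 1 lower, or 12 and 1 when adjusted over the list alone, with a median of 0.35. Beside Socs3 and Cebpd these included Junb (1.23) and Cish (1.07), a STAT-induced feedback inhibitor. The camera adjusted p was 4.8e-08, and adjusted p = 0.344 with an estimated correlation. The acute-phase proteins went both ways. Among 35 positive acute-phase proteins 4 were higher and 4 lower, or 5 and 8 when adjusted over the list alone, with a median of -0.04 (camera adjusted p = 0.544). The zinc transporter gene Slc39a14 rose by 1.00 and the fibrinogen genes Fga by 0.81 and Fgb by 0.58, while Saa4 differed by -0.99 and Vnn1 by -0.75. Saa1 (-0.07, adjusted p = 0.582) and Saa2 (-0.10, 0.516) did not pass, with Saa1 near the top of the array scale in both conditions. Among 17 negative acute-phase proteins Igf1 was higher (0.40, but adjusted p = 0.0557 after centring and 0.106 with the spline) and Ahsg (-0.92) and Apoa4 (-0.48) lower, or 1 and 8 when adjusted over the list alone, with a median of -0.21 and a camera adjusted p of 0.00253 (adjusted p = 0.546 with an estimated correlation and 0.144 without the time block). Its median turned to 0.001 in the 4 cells of 17 arrays and to 0.027 with the nuclear RNA index. Albumin, Alb, differed by -0.04 (adjusted p = 0.751). Of 29 complement and coagulation genes 1 was higher, Pros1 (0.90), and 13 were lower, among them Masp1 (-1.42), F13b (-0.95) and F10 (-0.85). When adjusted over the list alone these were 1 and 18, with a median of -0.29 and a camera adjusted p of 4.21e-07 (adjusted p = 0.49 with an estimated correlation and 0.311 in the 4 cells).

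Genes of hepatocyte metabolism were lower across several lists at the matched times. Of 46 cytochrome P450 and drug metabolism genes 24 were lower and 0 higher, or 38 and 0 when adjusted over the list alone, with a median of -0.63 (camera adjusted p = 6.1e-18). Beside Adh1 they included Fmo5 (-2.35), Ugt2b5 (-2.31) and Aox3 (-2.16). Of 37 gluconeogenesis and amino acid catabolism genes 21 were lower, or 25 when adjusted over the list alone, with a median of -0.64 (5.6e-12). They included Tdo2 (-1.78), which opens tryptophan breakdown, Gpt2 (-1.59) and Bhmt (-1.54). Of 33 fatty acid oxidation genes 19 were lower and 1 higher, or 24 and 1 when adjusted over the list alone, with a median of -0.45 (2.79e-12). Ehhadh (-1.54), Cd36 (-1.37) and Acot1 (-1.26) were among them. Of 28 bile acid and transporter genes 14 were lower, or 18 when adjusted over the list alone, with a median of -0.43 (5.17e-08), including the phospholipid transporter gene Abcb4 (-1.71), the bile acid receptor gene Nr1h4 (-1.26) and Cyp7b1 (-1.14), of which another probe set differed by 0.06. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.09 (adjusted p = 0.583), with its other probe set at -0.06. Of 23 liver-enriched transcription factors 10 were lower and 1 higher, or 12 and 1 when adjusted over the list alone, with a median of -0.28 (8.67e-07). Nr1i2, a nuclear receptor for foreign compounds, differed by -1.53, Klf15 by -1.30 and Creb3l3 by -1.14. Each of these 5 lists had adjusted p = 0.344 with an estimated correlation.

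Genes of growth factor signalling were among those higher at the matched times. Of 29 growth factor, receptor and invasion genes 9 were higher and 2 lower, or 12 and 2 when adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.000126). Inhba, a subunit of activin, rose by 1.24, the cytokine gene Lif by 1.05 and Cd44 by 0.98, although another probe set of Cd44 differed by -0.08. Met, the HGF receptor, was lower by 1.49-fold (-0.57 ± 0.08, SE; adjusted p = 0.013). Of 35 immediate early and ERK feedback genes 6 were higher and 2 lower, or 12 and 4 when adjusted over the list alone, with a median of 0.22 (0.000203). The feedback inhibitors Spred3 and Dusp5 rose by 1.62 and 1.17 and Ier3 by 0.76, while Dusp6 (0.27, adjusted p = 0.111) and Myc (0.16, 0.438) did not pass. Of 32 unfolded protein and amino acid stress genes 7 were higher and 1 lower, or 16 and 1 when adjusted over the list alone, with a median of 0.24 (1.36e-07). The secretory pathway chaperones Creld2 (0.78), Sdf2l1 (0.77) and Manf (0.69) were higher, and the cystine transporter gene Slc7a11 (-0.89) was lower. These 3 lists had adjusted p = 0.344 with an estimated correlation. Of 39 ribosome biogenesis genes 4 were higher, among them Rrp1b (0.46) and Rrp9 (0.35), or 5 when adjusted over the list alone, with a median of 0.11 and a camera adjusted p of 0.000124 (adjusted p = 0.38 with an estimated correlation).

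Few proliferation genes passed between IL-6 plus HGF and control at the same hour, and those that passed over all genes were lower. Of 36 G2 and mitosis genes 6 were lower and 0 higher, also when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 7.48e-07, adjusted p = 0.344 with an estimated correlation and 0.422 without the time block). They included Ttk (-0.60), the proliferation marker Mki67 (-0.55), Ccnb2 (-0.39, adjusted p = 0.0745 after quantile normalization) and Cenpf (-0.77), of which another probe set differed by 0.14. Of 39 DNA replication genes only Tk1 passed, at -0.76, also when adjusted over the list alone (median -0.06, camera adjusted p = 0.776). Of 25 G1 and G1/S genes 0 were higher and 1 lower, or 1 and 2 when adjusted over the list alone (median -0.01, camera adjusted p = 0.967). Ccnd1, which encodes cyclin D1, differed by -0.29 (adjusted p = 0.128) with another probe set at 0.17, and the cell cycle inhibitor gene Cdkn1a by 0.18 (0.208). Relative to control at 0 h the mean of the G2 and mitosis genes was 0.70, 1.28 and 3.04 at 8, 12 and 24 h with IL-6 plus HGF against 0.99, 1.45 and 3.22 in control, lower at each hour. The other lists went both ways: the mean of the DNA replication genes was -0.08, 0.08 and 1.00 against 0.03, 0.22 and 0.83. That of the G1 and G1/S genes was -0.06, 0.08 and 0.76 against 0.09, 0.13 and 0.63.

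Smaller groups at the matched times were mixed. Cholesterol synthesis genes were higher in 4 of 20 and lower in 1, or 7 and 1 when adjusted over the list alone, with Insig1 at 0.49 (adjusted p = 0.0557 after centring), Cyp51 at 0.45 and Dhcr7 at -0.61 (median 0.20, camera adjusted p = 0.00138, adjusted p = 0.572 with an estimated correlation). Fatty acid synthesis genes were lower in 5 of 20, or 1 higher and 5 lower when adjusted over the list alone (median -0.11, 0.0308, adjusted p = 0.572 with an estimated correlation), and this call was also lost after quantile normalization (adjusted p = 0.0979), without dim genes (0.25) and in the other fits of 17 arrays. Interferon response genes were lower in 6 of 24, or 9 when adjusted over the list alone, with Ifit1 at -0.64 and Ifit2 at -0.62 (median -0.18, 7.79e-06, adjusted p = 0.344 with an estimated correlation). Of 19 glycolysis genes Slc2a1 (0.52) and Pkm (0.50) were higher and the hepatic glucose transporter gene Slc2a2 (-1.88) lower, or 3 and 2 when adjusted over the list alone (median 0.01, 0.968). Of 26 glucocorticoid response genes 3 were higher and 6 lower, or 4 and 7 when adjusted over the list alone, with Tat at -0.85 (median -0.02, 0.485). NF-kB targets were higher in 2 of 29 and lower in 4, or 4 and 4 when adjusted over the list alone, with the chemokine gene Ccl2 at -0.91 (median 0.02, 0.978). Of 42 cytoskeleton genes 7 were higher and 1 lower, the same counts as when adjusted over the list alone, with Ankrd1 at 0.80 and Ccn2 at 0.60 (median 0.03, 0.156). Of 17 clock genes Bhlhe40 (0.45) was higher and Cry2 (-0.39) lower, also when adjusted over the list alone (median -0.07, 0.9). The medians of the G1, glycolysis, NF-kB, cytoskeleton and lymphocyte lists lay within 0.05 of 0 under each scaling and on either side of it, so no direction is given for them.

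Markers of other liver cells were also read at the matched times. Of 21 macrophage markers Cd68 was lower (-0.73), and 0 passed when adjusted over the list alone (median -0.15, camera adjusted p = 0.0202, adjusted p = 0.577 with an estimated correlation and 0.0526 without the time block). Of 21 endothelial markers 2 were lower, or 6 when adjusted over the list alone (median -0.11, 0.0067, adjusted p = 0.355 with an estimated correlation and 0.118 without dim genes); Clec4g differed by -0.70 with another probe set at 0.00. Of 22 stellate and fibroblast markers Rgs5 was lower (-0.36), and 0 passed when adjusted over the list alone (median -0.01, 0.935). Of 12 cholangiocyte markers Cldn4 (1.16) and Sox9 (0.55) were higher and Pkhd1 (-0.88) lower, also when adjusted over the list alone (median 0.09, 0.156). Of 19 lymphocyte and blood cell markers 0 passed in limma over all genes or over the list alone (median 0.02, 0.318).

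**Figure D2:**
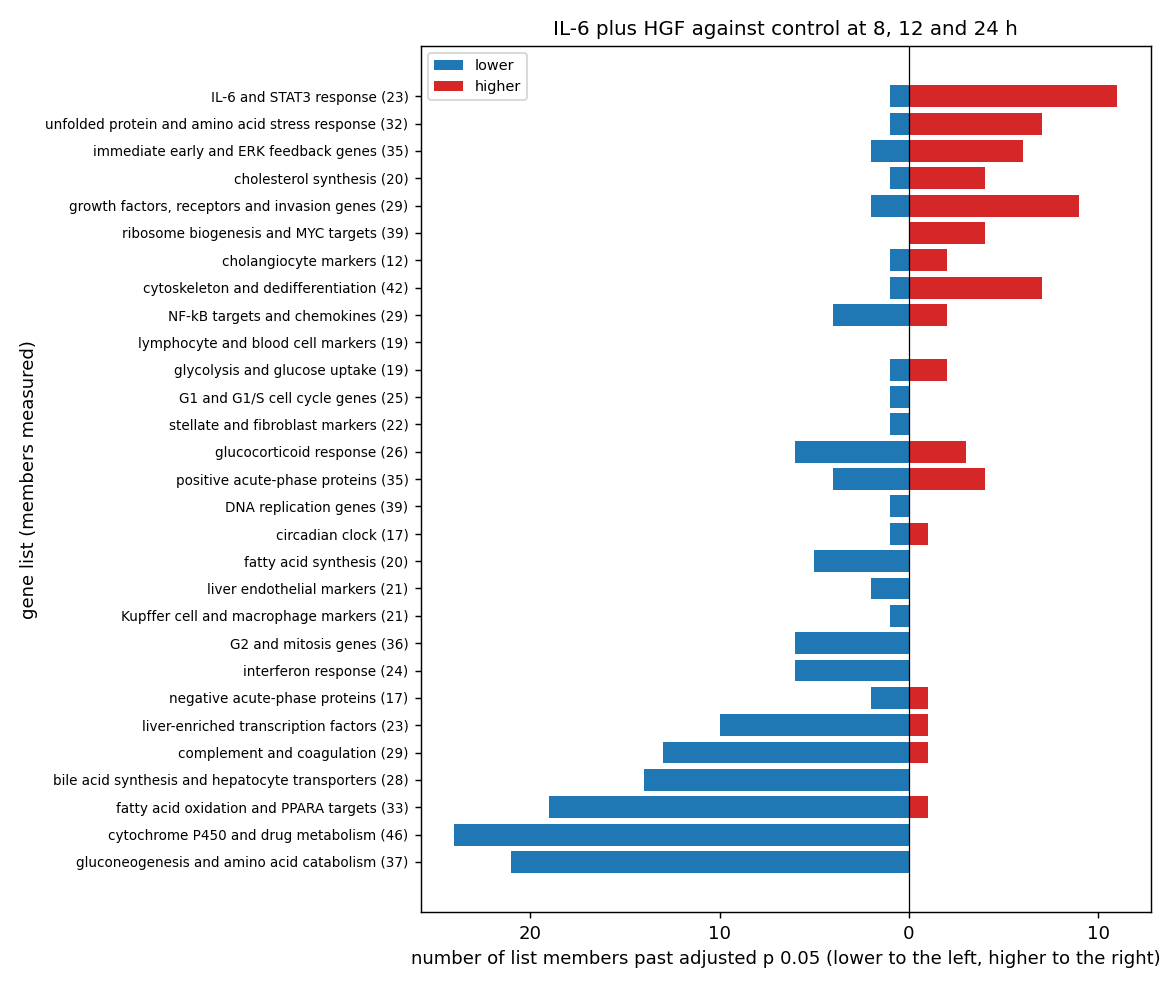
Number of members of each of the 29 gene lists past an adjusted p of 0.05 at the matched times, lower to the left and higher to the right, with the number of members measured in brackets and lists ordered by their median difference. The drug metabolism list had 24 lower members and the IL-6 and STAT3 list 11 higher members.

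The effect of IL-6 plus HGF was then set against that of IL-6 alone, each against its own controls. Arrdc3, an arrestin-domain gene, had effects of 0.05 with IL-6 and -1.99 with IL-6 plus HGF, a difference of -2.04 ± 0.28 (SE; adjusted p = 0.0136). Nudt12 had effects of 0.04 and -1.20 and a difference of -1.24 ± 0.20 (0.048). Hmga2-ps1, annotated as a pseudogene of Hmga2, had effects of 0.01 and 1.36 and a difference of 1.36 ± 0.19 (0.0136). Pmepa1, an inhibitor of TGF-beta signalling, had effects of 0.03 and 1.20 and a difference of 1.17 ± 0.19 (0.048). The receptor gene Nr1i2 (-1.28), the ketone body enzyme gene Bdh1 (-1.75) and Lif (1.36) did not pass (adjusted p = 0.0998 each), nor did Socs3 (-0.53, 0.832). With arrays centred on their median Nudt12 (adjusted p = 0.0784) and Pmepa1 (0.0522) missed the threshold, the latter also as the mean of its probe sets (0.137). In limma 2 genes were higher and 2 lower, and 1419 had an unadjusted p under 0.05. These counts rested on single arrays: 0 and 0 remained without the control at 0 h or the IL-6 array at 2 h, and 8 and 18 were called without the control at 4 h. They were 1 and 4 without the control at 8 h or at 24 h, 1 and 0 without that at 12 h, and 1 and 1 without any of the IL-6 arrays at 1, 3 or 4 h or the IL-6 plus HGF arrays at 7, 8 or 9 h. They were 2 and 1 without the array at 5 h, 2 and 7 without that at 6 h, 2 and 6 without that at 12 h, and 3 and 9 without all 24 h arrays.

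Camera called 15 lists in this difference, and 0 with an estimated correlation or with fry. Fatty acid oxidation genes had a median of -0.34 (adjusted p = 4.25e-08, and adjusted p = 0.116 with an estimated correlation), with 0 of 33 members past limma's threshold over all genes and 6 lower when adjusted over the list alone. Liver-enriched transcription factors had a median of -0.35 (7.92e-07, adjusted p = 0.0812 with an estimated correlation), with 0 of 23 over all genes and 7 lower when adjusted over the list alone. The unfolded protein list had a median of 0.24 (8.3e-07, adjusted p = 0.0981 with an estimated correlation), with 0 of 32 and 1 higher. The ribosome biogenesis list had a median of 0.18 (1.1e-07, adjusted p = 0.328 with an estimated correlation), with 0 of 39 on either adjustment. The G2 and mitosis list had 35 of 36 negative values and a median of -0.81 (1.93e-05, adjusted p = 0.671 with an estimated correlation), with 0 past limma's threshold on either adjustment. Markers of other cells differed too: macrophage markers had a median of 0.24 (0.000603, adjusted p = 0.214 with an estimated correlation) and cholangiocyte markers of 0.13 (0.0432, adjusted p = 0.145 with an estimated correlation, lost after quantile normalization at 0.0669), each with 0 past limma's threshold over all genes and 1 higher when adjusted over the list alone. The mean sampling time was 14.7 h for the late controls and 10.1 h for IL-6 plus HGF. Without the control at 24 h the mitosis median was -0.11 (adjusted p = 0.597).

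The time trend under IL-6 plus HGF was the slope of 8 arrays per doubling of the hours from 5 to 24 h. Mitosis genes were among the steepest rises: Depdc1a rose by 1.98 ± 0.35 (SE; adjusted p = 0.00553), the spindle checkpoint gene Bub1 by 1.73 ± 0.26 (0.00246), Ccnb2, which encodes cyclin B2, by 1.70 ± 0.13 (0.000111), Nusap1 by 1.59 ± 0.23 (0.00175) and Ttk by 1.56 ± 0.18 (0.000613). Ccnb2 went from 6.03 at 5 h to 9.74 at 24 h. Of 36 G2 and mitosis genes 34 rose, or 36 when adjusted over the list alone, with a median slope of 1.20 (camera adjusted p = 1.78e-34, adjusted p = 0.123 with an estimated correlation). Of 39 DNA replication genes 17 rose, or 34 when adjusted over the list alone, with Cdc6 at 0.97, Rrm2 at 0.93 and Mcm10 at 0.71 (median 0.41, 1.41e-16, adjusted p = 0.238 with an estimated correlation). Of 25 G1 and G1/S genes 12 rose, or 15 rose and 1 fell when adjusted over the list alone, with Ccne2 at 1.10 and E2f7 at 0.91 (median 0.33, 2.47e-07, adjusted p = 0.293 with an estimated correlation). Ccnd1 had a slope of 0.51 (adjusted p = 0.146). The replication and G1 trends rested on the array at 24 h: without it their medians were 0.00 (camera adjusted p = 0.814) and 0.02 (0.852), against 0.51 for the mitosis list, which was still called.

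Over the same hours hepatocyte functions declined. Cyp2b10, a drug-inducible cytochrome P450, fell by 1.80 ± 0.06 per doubling (SE; adjusted p = 9.08e-07), from 10.44 at 5 h to 6.52 at 24 h. Rdh7 had a slope of -2.14, Cyp3a11 of -1.98, Sult1a1 of -1.96, the urea cycle gene Cps1 of -1.86, the fatty acid binding protein gene Fabp1 of -1.80, Gnmt of -1.74 and Cyp2e1 of -1.64. Of 46 drug metabolism genes 38 fell, or 42 when adjusted over the list alone, with a median slope of -0.89 (camera adjusted p = 2.59e-37, adjusted p = 0.0454 with an estimated correlation). Of 37 gluconeogenesis genes 25 fell, or 1 rose and 29 fell when adjusted over the list alone (median -0.35, 4.21e-19, adjusted p = 0.0454 with an estimated correlation). Of 28 bile acid and transporter genes 1 rose and 11 fell, or 2 and 13 when adjusted over the list alone, with Baat at -1.53 (median -0.19, 6.94e-06, adjusted p = 0.0454 with an estimated correlation). Of 20 cholesterol synthesis genes 15 fell, or 18 when adjusted over the list alone, with Hmgcs1 at -0.73 (median -0.40, 5.18e-16, adjusted p = 0.0934 with an estimated correlation). Of 39 ribosome biogenesis genes 9 fell, or 15 when adjusted over the list alone (median -0.12, 6.05e-07, adjusted p = 0.0454 with an estimated correlation). Slc2a2 had a slope of -1.22 and Pkm, the pyruvate kinase of proliferating cells, of 0.73.

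Many genes of secreted liver proteins also fell with time under IL-6 plus HGF. Relative to control at 0 h the list means at 24 h with IL-6 plus HGF and in control were -0.73 and -0.68 for positive acute-phase proteins, -1.02 and -0.74 for negative ones, and -1.07 and -0.70 for complement and coagulation. Of 35 positive acute-phase proteins 1 rose and 17 fell, or 1 and 25 when adjusted over the list alone, with a median slope of -0.28 (camera adjusted p = 2.35e-13, adjusted p = 0.0842 with an estimated correlation). Crp had a slope of -1.01, Saa2 of -0.61 and Saa1 of -0.38 (adjusted p = 0.00456), while Fgb at -0.08 did not pass (0.408). Of 17 negative acute-phase proteins 12 fell, also when adjusted over the list alone, with Serpina6 at -0.78 (median -0.45, 3.74e-11, adjusted p = 0.123 with an estimated correlation). Of 29 complement and coagulation genes 2 rose and 18 fell, or 2 and 20 when adjusted over the list alone (median -0.48, 1.36e-12, adjusted p = 0.125 with an estimated correlation). Masp1 had a slope of -1.55, although 4 of its 5 probe sets did not share that direction and their mean did not pass (adjusted p = 0.379). Of 23 IL-6 and STAT3 genes 1 rose and 6 fell, or 1 and 9 when adjusted over the list alone (median -0.19, 0.000855, adjusted p = 0.113 with an estimated correlation), and Socs3 at -0.56 did not pass (0.0538). Relative to control at 0 h the mean of that list was 0.69 at 5 h and 0.25 at 24 h, against -0.22 in control at 24 h. Of 35 immediate early genes 4 rose and 8 fell, or 5 and 12 when adjusted over the list alone (median -0.14, 0.0207, adjusted p = 0.52 with an estimated correlation), with Egr1 at -1.02, Dusp5 at -0.81 and Fosl1 at -0.73. Timp1 rose by 1.00, Cd44 by 0.81 and the cholangiocyte keratin gene Krt19 by 1.02, and the endothelial receptor gene Lyve1 had a slope of -1.28. The muscle gene Tnnt2 had the steepest rise, at 2.10, although another of its 3 probe sets had a slope of -0.03, as did another of the 4 of Cd44.

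In limma 1140 genes rose and 880 fell with time under IL-6 plus HGF, and 4219 had an unadjusted p under 0.05. Of these, 75 rose and 73 fell by at least 1 log2 per doubling. Without the array at 24 h limma called 50 and 194, and 201 of the 2020 genes were among them; Ccnb2 and Ttk then still passed, as did Cyp2b10, Cps1, Fabp1 and Gnmt, whereas Bub1, Depdc1a, Nusap1, Saa1 and Timp1 did not. Without the array at 10 h it called 1769 and 1326, including all 2020. On that array Malat1 lay 1.63 and Neat1 2.36 above the mean of the 9 h and 12 h arrays, 2 nuclear RNAs chosen after their values were seen.

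**Figure D3:**
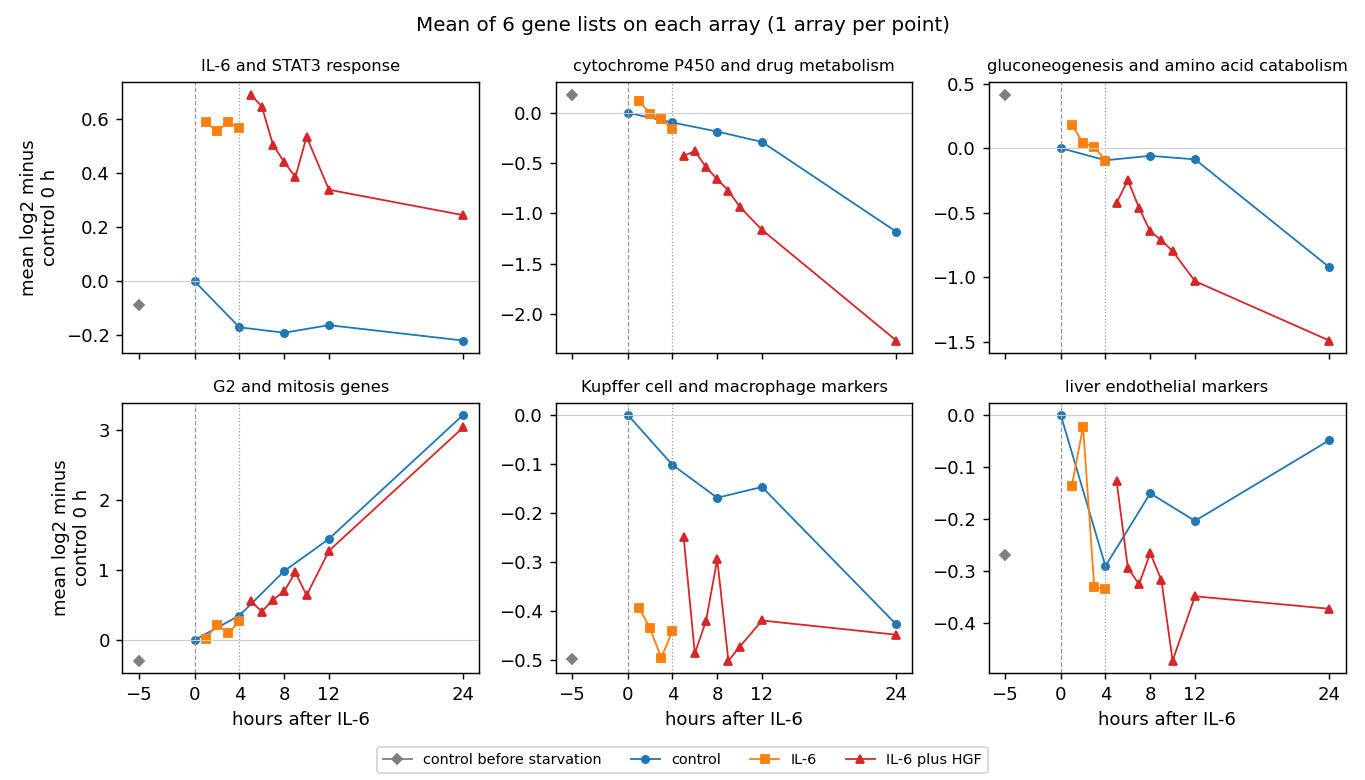
Mean log2 value of 6 gene lists on each array minus that on the control at 0 h, against hours after IL-6, 1 array per point, coloured by stimulus; the dashed and dotted lines mark IL-6 at 0 h and HGF at 4 h. At 24 h the drug metabolism list lay at -2.27 with IL-6 plus HGF and -1.18 in control, and the G2 and mitosis list at 3.04 and 3.22.

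The time trend under IL-6 plus HGF was compared with that in control from 4 to 24 h. Sult1e1, a sulfotransferase that inactivates oestrogen, had slopes of 0.39 with IL-6 plus HGF and -1.07 in control, a difference of 1.46 ± 0.20 (SE; adjusted p = 0.0259). Havcr1 had slopes of 0.99 and -0.15, a difference of 1.14 ± 0.13 (0.00999). Ggct differed by 1.00 and Acsbg1 by 0.99. Ugt2b36 had slopes of -0.80 and 0.17, a difference of -0.97 ± 0.11 (0.00999), and Gsta3, a glutathione transferase, slopes of -0.87 and 0.16, a difference of -1.03 ± 0.15 (0.0268). Adhfe1 differed by -1.07, Hsd17b2 by -0.96, the acetyl-CoA synthetase gene Acss2 by -0.52 and the gluconeogenic gene Fbp1 by -0.50. Of 46 drug metabolism genes 44 had a steeper fall or weaker rise with IL-6 plus HGF, with a median of -0.34; 2 passed over all genes and 17 when adjusted over the list alone (camera adjusted p = 2.24e-25, adjusted p = 0.134 with an estimated correlation). Of 37 gluconeogenesis genes 1 was lower, or 6 when adjusted over the list alone (median -0.25, 3.27e-08, adjusted p = 0.274 with an estimated correlation). Lists of markers of other cells were called as well: of 21 endothelial markers 0 passed in limma and 3 were lower when adjusted over the list alone (median -0.16, 6.79e-06, adjusted p = 0.134 with an estimated correlation). Of 21 macrophage markers 0 passed on either adjustment (median 0.06, 0.0479, adjusted p = 0.611 with an estimated correlation), a call lost in several settings and a median that turned to -0.10 without the 24 h arrays. Medians of secreted protein lists were also lower, at -0.20 for complement and coagulation (2.17e-06), -0.14 for negative (0.00191) and -0.13 for positive acute-phase proteins (0.000626), each lost with an estimated correlation (adjusted p between 0.386 and 0.547), with 0 members past limma's threshold on either adjustment. The slopes of the G2 and mitosis list differed by a median of 0.01 (camera adjusted p = 0.475), with 0 of 36 past limma's threshold on either adjustment. Of 39 DNA replication genes 36 had a steeper slope with IL-6 plus HGF and 0 passed in limma on either adjustment (median 0.12, camera adjusted p = 0.00658, adjusted p = 0.704 with an estimated correlation). Of 25 G1 and G1/S genes 18 had a steeper slope and 0 passed (median 0.07, 0.0223, adjusted p = 0.692 with an estimated correlation). Both medians changed sign without the 24 h arrays, to -0.11 and -0.13, and without the control at 4 h, to -0.07 and -0.03.

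In limma 7 genes had a higher and 11 a lower slope with IL-6 plus HGF, and 1144 had an unadjusted p under 0.05. Without the control at 4 h 0 and 0 were called, without that at 8 h 3 and 3, without that at 12 h 4 and 12, and without that at 24 h 1 and 16. Without the IL-6 plus HGF array at 5 h they were 14 and 25, at 6 h 2 and 1, at 7 h 3 and 3, at 8 h 4 and 3, at 9 h 5 and 4, at 10 h 17 and 27, at 12 h 4 and 9, and at 24 h 0 and 4. None of the 18 genes was among those called without both 24 h arrays (0 and 1). The slope on hours gave 20 and 26, an intensity trend with robust variance 15 and 27, and the mean of all probe sets 4 and 7. With that mean Acsbg1 (adjusted p = 0.0539), Adhfe1 (0.0539) and Acss2 (0.0935) were lost, and with the slope on hours Adhfe1 (0.0512), Hsd17b2 (0.0652) and Fbp1 (0.161). Camera called 17 lists, 0 with an estimated correlation or with fry, and 10 without the control at 4 h, where the gluconeogenesis call was lost (median -0.09, adjusted p = 0.815).

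Unstimulated cells changed with time in culture as well. Mitosis genes rose per doubling of the hours plus 1: Nusap1 by 1.01 ± 0.17 (SE; adjusted p = 0.0342), Ube2c by 0.95 ± 0.16 (0.0363), the apoptosis inhibitor gene Birc5 by 0.91 ± 0.13 (0.0256), Mki67 by 0.91 ± 0.15 (0.0337), Plk1 by 0.88 and Ccna2 by 0.73. Nusap1 went from 4.65 at 0 h to 9.78 at 24 h. Of 36 G2 and mitosis genes 8 rose, or 35 when adjusted over the list alone, and all 36 slopes were positive, with a median of 0.62 (camera adjusted p = 1.13e-18, adjusted p = 0.538 with an estimated correlation). Cyp2b10 fell by 0.91 ± 0.16 (0.0383) and Cyp1a1 by 0.90 ± 0.13 (0.0251), and of 46 drug metabolism genes 2 rose and 9 fell, or 5 and 21 when adjusted over the list alone (median -0.26, 0.000182, adjusted p = 0.538 with an estimated correlation). Of 20 cholesterol synthesis genes 7 fell, or 17 when adjusted over the list alone, with Hmgcs1 at -0.28 (median -0.18, 8.92e-14, adjusted p = 0.435 with an estimated correlation). Of 39 ribosome biogenesis genes 8 fell, or 21 when adjusted over the list alone (median -0.11, 2.45e-13, adjusted p = 0.435 with an estimated correlation). Glucocorticoid-responsive genes fell in 6 of 26 and rose in 1, or 7 and 2 when adjusted over the list alone, with Sult1e1 at -0.64, Mt1 at -0.46 and Tat at -0.46 (median -0.04, 0.0581). Some genes of secreted liver proteins fell in control too: of 35 positive acute-phase proteins 3 rose and 5 fell, or 3 and 11 when adjusted over the list alone (median -0.12, 6.56e-05), of 17 negative ones 1 fell on either adjustment (-0.11, 7.43e-05), and of 29 complement and coagulation genes 1 rose and 2 fell, or 2 and 5 when adjusted over the list alone (-0.12, 0.00508), each with adjusted p = 0.538 with an estimated correlation. Crp had a slope of -0.59, Dusp5 of -0.39, the macrophage receptor gene Marco of -0.42 and Lyve1 of -0.50, while the collagen gene Col3a1 rose by 0.37, Lgals1 by 0.50 and Vnn1 by 0.51. Of 21 macrophage markers 2 fell, or 2 rose and 7 fell when adjusted over the list alone (median -0.045, camera adjusted p = 0.0128, adjusted p = 0.502 with an estimated correlation).

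In limma 390 genes rose and 267 fell in control, 1 and 0 of them by at least 1 log2 per doubling, and 4077 had an unadjusted p under 0.05. With an intensity trend and robust variance the 6 mitosis genes named above missed the threshold (adjusted p between 0.0537 for Birc5 and 0.103 for Plk1), as did Cyp2b10 (0.0894), Cyp1a1 (0.0504) and Sult1e1 (0.0937). Without the control at 0 h 194 and 101 were called, without that at 4 h 14 and 9, without that at 8 h 20 and 12, and without that at 12 h 104 and 66. Of the 657 genes 106, 23, 32 and 154 were among them in that order. Without the control at 24 h 436 of the 657 were still called in the same direction. Camera called 17 lists, 0 with an estimated correlation, 6 by fry and 11 without the control at 24 h. The fit of the 5 controls left 3 residual degrees of freedom, which limits what camera with an estimated correlation can call. The trend in control and that under IL-6 plus HGF came from 5 and 8 arrays with none in common. Of the 657 genes called in control and the 2020 called under IL-6 plus HGF, 355 were called in both in the same direction, where 37.4 would be shared by independent lists, and 5 in opposite directions.

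The control at -5 h was set against the 5 later controls. By the hours of the protocol it would precede the withdrawal of the synthetic glucocorticoid dexamethasone, but no label states its medium, so a glucocorticoid reading of these differences is an inference. No gene passed in limma (0 higher and 0 lower), and 1019 had an unadjusted p under 0.05. The glucocorticoid-induced gene Fkbp5 stood at 10.59 at -5 h against 9.71 ± 0.08 (SD, n = 5) later, a limma difference of 0.89 (adjusted p = 0.607), and the clock gene Per1 differed by 1.11 (0.76). Tat differed by 1.50, the gluconeogenic gene Pck1 by 1.70 and Cyp2b10 by 2.52, with adjusted p between 0.838 and 0.84. Of 26 glucocorticoid-responsive genes 21 had higher values at -5 h, with a median of 0.40, and 4 were higher when adjusted over the list alone (camera adjusted p = 2.61e-06, adjusted p = 0.164 with an estimated correlation). Of 24 interferon response genes 20 had higher values, with Ifit1 at 1.27 and Rsad2 at 1.50, and 1 was higher when adjusted over the list alone (median 0.35, 6.76e-08, adjusted p = 0.341 with an estimated correlation). Gluconeogenesis genes had a median of 0.55, with 0 of 37 past limma's threshold on either adjustment (1.7e-06, adjusted p = 0.468 with an estimated correlation). All 36 mitosis genes had lower values at -5 h, with a median of -1.51, Birc5 at -2.87 and Ttk at -2.59, and 0 past limma's threshold on either adjustment (4.74e-08, adjusted p = 0.591 with an estimated correlation). Much of this came from the later rise in control: the mean of the list at -5 h lay 0.30 below that of the control at 0 h, and the median against the controls at 0 and 4 h alone was -0.47. Of 21 macrophage markers 6 were lower when adjusted over the list alone (median -0.34, 1.91e-05, adjusted p = 0.463 with an estimated correlation), with Ptprc at -1.58. Kdr differed by -1.02 and Lpl by -0.95. Other probe sets of Ttk and Ptprc differed by 0.04 and 0.20. Only 1 array stood at -5 h, and it was assumed to vary like the later controls. Against the controls at 0 and 4 h alone, within a fit of all 18 arrays, 1 gene passed, Fkbp5 (0.82, adjusted p = 0.0313), while the drug metabolism list, with a median of 0.52 against all later controls (camera adjusted p = 0.00412, adjusted p = 0.591 with an estimated correlation, 0 of 46 past limma's threshold), lost its call (0.123). Camera called 17 lists, 0 with an estimated correlation or with fry.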

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

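The tests of the rising mitosis genes in control were chosen after that result was seen; the splits of the arrays were set before it. The control array at 24 h stood apart from the other controls in its upper quartile, at 7.949 log2 (gap of 0.792 of the range), and in its mean correlation with the other arrays, at 0.9855 (gap of 0.823). Of 28 sets of values tested for such a gap these 2 stood apart, where about 1 in 20 would by chance. The IL-6 plus HGF array at 24 h had the lowest mean correlation of all (0.9852) and the highest upper quartile of its group (7.902), so both last arrays lay to the same side. The gap alone does not separate a late culture effect from a property of that dish.

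The rise of mitosis genes in unstimulated cells ended on the same array. If that array alone made the rise, the median slope without it would be near 0, and it was 0.343, which argued against this explanation. If the 24 h control had received IL-6 and HGF by mistake, its IL-6 and STAT3 genes would equal those of the stimulated dish, and they differed by 0.464, which argued against that too. If other liver cells had overgrown the dish, their markers would rise: the highest median slope among stellate, endothelial and macrophage markers was 0.012, but of 22 stellate and fibroblast markers 2 rose over all genes and 11 had positive slopes (limma's fry adjusted p = 0.0435, camera 0.285), so overgrowth remains open. Entry of unstimulated hepatocytes into the cell cycle also remains open, and no biological explanation was tested.

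The effect of the stimulus differed between IL-6 plus HGF and IL-6 alone for Arrdc3 (-2.04), Hmga2-ps1 (1.36), Nudt12 (-1.24) and Pmepa1 (1.17). The late controls were sampled at a mean of 14.7 h and the IL-6 plus HGF arrays at 10.1 h, whereas the early controls and IL-6 arrays lay at 2 and 2.5 h. Culture time is thus not balanced in this difference. Whether HGF or longer IL-6 set these genes apart was not tested.

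The time slope was higher under IL-6 plus HGF than in control for 7 genes and lower for 11. The 12 arrays can be split into 8 and 4 in 495 ways, and 100 of these splits, the real one among them, were refitted. In 13 of the 100 at least as many genes passed, with up to 718, and in 8 of the 100 at least as many lists were called, with up to 22 against 17. The real split is included in these shares. The splits did not keep the hours of each group, so change over time common to all arrays could enter the tested term. They therefore do not measure chance alone. Chance is not excluded for these counts, and splits with several times the real count point to a structure of the samples, whose nature was not examined.

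Among probe sets without a single gene symbol, controls left out, 189 of 10092 passed at the matched times, 89 higher and 100 lower with IL-6 plus HGF. They were tested like the genes and are outside every count of genes in the report. The 6 arrays of the matched times allow 10 splits into 3 and 3. Only the real split, 1 of 10, had as many genes as the 1637 found, the highest other having 0, and 1 of 10 had as many lists as the 18 called, the highest other having 17. Among splits that part the arrays of all 3 hours the highest other had 13. Every other split called at least 9 lists while calling 0 genes. The time block was kept in these fits. A split that parts only 1 hour thus set the stimulus against control at that hour, and the remaining ones turned a pair around. Part of the stimulus effect stayed in each, so their counts do not show what camera calls without an effect. Camera's p-values at the preset correlation were not set against such groupings, and alone they remain weak evidence. With 10 splits the share cannot fall under 0.05, so the splits cannot tell chance from effect here, and no biological explanation was tested.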

How the results depend on the processing

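The nuclear RNA index was added after the results had been seen; every other setting was set before. With the replicate block, here the pairing by hour, left out at the matched times, limma called 48 genes higher and 94 lower in place of 461 and 1176, and 142 of the 1637 were kept. The negative acute-phase (adjusted p = 0.144), mitosis (0.422) and macrophage (0.0526) lists also lost their calls without the block.

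For IL-6 against control, hours as a covariate in 6 arrays gave 8 higher, 1 lower and 10 lists; the 6 arrays alone 8 lists; all 5 controls 20 higher, 2 lower and 15 lists; estimated correlation 2 lists and fry 2. Saa1 changed sign to 0.183 and Saa2 to 0.303 with all 5 controls, and Saa2 to 0.051 with the nuclear RNA index; the cause was not tested. Leaving out an IL-6 array gave 4 or 5 higher, 0 lower and 3 to 6 lists. Leaving out a control at 0 or 4 h leaves 1 array in that cell, so no count is given for it. The controls after 4 h and the IL-6 plus HGF arrays, which share in the variance of this fit, were not left out in turn.

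At the matched times a log2 difference of at least 1 left 49 higher and 150 lower, the spline gave 1056 and 2096, and the 4 cells with the nuclear RNA index 560 lower. Estimated correlation and fry called 0 lists each, against 18. Quantile normalization kept 1283 of the 1637 genes, centring 1536, the dim filter 1440, the mean of probe sets 1213 (6 of all 1637 with opposite sign), the 4 cells 1031 (16) and the 4 cells with the nuclear RNA index 641 (39). In the 4 cells the sign changed for the negative acute-phase median (0.001), Saa1 (0.095), Saa2 (0.139) and Alb (0.001), and with the nuclear RNA index for that median (0.027), Saa1 (0.194), Saa2 (0.333), Pkm (-0.014), Rgs5 (0.036) and Alb (0.014); the cause was not tested. Cyp7a1 changed sign to -0.004 without the pair at 24 h (highest 0.189); the cause was not tested. Complement and coagulation lost its call in the 4 cells (adjusted p = 0.311). Without 1 pair 178 to 228 genes were higher, 407 to 615 lower and 16 to 18 lists called.

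For the change of effect centring gave 1 higher and 1 lower, the mean of probe sets 1 higher, no 24 h arrays 9 lower, and estimated correlation and fry 0 lists each. The drug metabolism median changed sign to 0.043 without the control at 8 h and 0.067 without IL-6 plus HGF at 24 h, and DNA replication to 0.039 without the control at 24 h; the cause was not tested. Over all arrays left out the medians ran from -0.449 to 0.067 and from -0.355 to 0.039. Leaving out an array gave 0 to 8 higher, 0 to 18 lower and 13 to 16 lists.

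For the trend under IL-6 plus HGF a slope of at least 1 left 75 and 73 genes, no 24 h array 50 and 194, and estimated correlation 4 lists. By fry, with the 24 h array included, the mitosis (adjusted p = 0.00292), DNA replication (0.024), G1 (0.0459) and positive acute-phase (0.000801) lists kept their calls. Every other list called by camera was also kept by fry, among them IL-6 and STAT3 (0.00674), drug metabolism (0.000206) and cholesterol synthesis (0.000801). Only the immediate early list lost its call by fry (0.149). The glucocorticoid list, not called by camera (0.058), was called by fry (0.00659). Without the 24 h array Rrm2 (-0.004), Ccnd1 (-0.253) and Fgb (0.028) changed sign; the cause was not tested. Over all arrays left out their slopes ran from -0.004 to 1.236, from -0.253 to 0.673 and from -0.125 to 0.028. Leaving out an array gave 50 to 1769 rising, 194 to 1326 falling and 15 to 16 lists.

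For the difference of trends the dim filter gave 20 lower, the intensity trend with robust variance 15 and 27, and the mean of probe sets 4 and 7. A difference of at least 1 left 3 and 2, no 24 h arrays 0 and 1, the nuclear RNA index 12 and 23, hours 20 and 26, and estimated correlation and fry 0 lists each. Medians changed sign without 24 h arrays for G1 (-0.132), DNA replication (-0.112) and macrophage (-0.102); without control 4 h for negative acute-phase (0.016), G1 (-0.027) and DNA replication (-0.073); without control 24 h for cytoskeleton (0.013). They also changed sign without IL-6 plus HGF at 5 h for immediate early genes (0.019) and cytoskeleton (0.008), and without that at 24 h for positive acute-phase (0.007), G1 (-0.183) and DNA replication (-0.287); the cause was not tested. Over all arrays left out the medians ran from -0.345 to 0.007 for positive and -0.282 to 0.016 for negative acute-phase proteins, -0.176 to 0.019 for immediate early genes, -0.183 to 0.232 for G1, -0.287 to 0.298 for DNA replication and -0.137 to 0.013 for cytoskeleton. Leaving out an array gave 0 to 17 higher, 0 to 27 lower and 10 to 18 lists.

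For the control at -5 h the 5 cells gave 1 higher, estimated correlation and fry 0 lists each, and the cholesterol median changed sign to -0.079 in the 5 cells; the cause was not tested. Leaving out a control gave 0 and 0 genes and 16 to 18 lists. For the control trend the dim filter gave 606 rising, a slope of at least 1 left 1 and 0, hours gave 1123 and 562, estimated correlation 0 lists and fry 6. The NF-kB median changed sign to 0.005 without the control at 24 h (lowest -0.047); the cause was not tested. Leaving out an array gave 14 to 391 rising, 9 to 275 falling and 11 to 18 lists. With 1 array per time, simulated differences of 0.5 log2 were recovered in 19.4% at the matched times and 4.5% at -5 h. In the control trend 91% of simulated slopes of 0.5 log2 per doubling were recovered. Such a slope makes a larger change over the hours sampled, so this share cannot be set against the other shares.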

Other observations

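The nuclear gene list and the 2 nuclear RNAs of this part were chosen after array values had been seen, and the bounds of every test here were set before its result. Between the last array with IL-6 alone and the first after HGF, values of hepatocyte functions stepped down within 1 hour. Relative to control at 0 h the mean of the drug metabolism genes was -0.16 at 4 h with IL-6 and -0.43 at 5 h with IL-6 plus HGF, and then -0.38 at 6 h and -2.27 at 24 h. The mean of the gluconeogenesis genes went from -0.10 to -0.42 over the same hour, back to -0.25 at 6 h and to -1.49 at 24 h. That of the fatty acid oxidation genes was -0.04 at 4 h, -0.23 at 5 h, -0.15 at 6 h and -0.80 at 24 h, so part of each step was undone an hour later. Other lists also moved at 5 h and returned at 6 h: at 4, 5 and 6 h the DNA replication mean was -0.10, 0.12 and -0.18, the interferon mean -0.15, -0.29 and -0.07 and the macrophage mean -0.44, -0.25 and -0.49. The array at 5 h thus stood apart in several lists, and the step is not particular to hepatocyte functions. Egr1, an early target of growth factor signalling, stood at 11.37 at 4 h, 12.67 at 5 h, 11.61 at 6 h and 9.97 at 24 h; it had also stood at 12.29 at 1 h after IL-6, against 10.39 in control at 0 h. With 1 array at each hour these steps have no replicate, and they were not tested.

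The IL-6 plus HGF array at 10 h departed from its neighbours: 137 genes lay more than 1 log2 from the mean of the 9 h and 12 h arrays, 120 of them higher and 17 lower. For the array at 8 h 0 genes lay as far from the mean of the 7 h and 9 h arrays, which are closer in time. No other array was set against its neighbours in this way. If that sample held a higher share of nuclear or unspliced RNA, other nuclear RNAs would be raised with Malat1 (1.63) and Neat1 (2.36). The median departure of 20 nuclear genes was 0.406, as this explanation predicts. The list was chosen after array values had been seen, and no other set of genes was set beside it. Most departing genes were higher, so this value does not single out nuclear RNA. The same array also had the highest 3' to 5' difference of actin (0.338) and the highest spike-in signals (9.26 for BioB and 13.91 for Cre, log2), so RNA quality and the amount of sample RNA also remain open and were not tested. At the matched times Malat1 differed by 1.56 (limma adjusted p = 0.00901, lost with an intensity trend and robust variance at 0.0661 and without the time block at 0.0764). Its level was 11.52 in unstimulated cells at 0 h and 9.16 with IL-6 plus HGF at 6 h, so it did not follow the stimulus throughout. Neat1 differed by 0.17 (0.865) and the nuclear list by a median of 0.166, which cannot tell a shift of nuclear RNA from a change of Malat1. No biological explanation was tested.

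Macrophage markers were lower with IL-6 in the first 4 hours. If drift with culture time lowered them, hours as a covariate would bring the median to near 0, and it was -0.448. The controls lay at a mean of 2 h and the IL-6 arrays at 2.5 h, so this covariate could move the median little. Relative to control at 0 h the list mean was -0.102 in control at 4 h and -0.44 with IL-6 at 4 h. This argues against a steady drift, but drift that is not steady cannot be excluded. If all non-parenchymal cells were fewer on the IL-6 dishes, endothelial markers would be as low, and their median was -0.05. Relative to control at 0 h their list mean was -0.291 in control at 4 h and between -0.335 and -0.023 with IL-6. The endothelial difference thus depends on which control is used. If a single control set the difference, it would vanish without it, and the medians were -0.416 without the control at 0 h and -0.51 without that at 4 h. Fewer non-parenchymal cells of every kind and a single control were thus argued against. A macrophage content that differs between dishes remains open, since the controls themselves ranged down to -0.50 at -5 h and -0.43 at 24 h. An effect of IL-6 on these cells is also open and was not tested.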
